A study of Homo sapiens with 10 samples.

How the data were processed

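Mononuclear cells were isolated from tonsil by density gradient, and GC B cells were sorted by surface markers, per the labels' protocols. Donors 1 and 2 were captured with the 3' kit version 2 and donor 3 with version 3 and CITE-seq, in which antibodies carry sequence tags, per the labels. The series names 3 donors without tying titles to them; the number in each title was taken as the donor. Bases were called with CASAVA 1.8 and reads counted on GRCh38 with Cell Ranger 2.1 and 3.0, per the submitters' processing notes, which do not tie a version to a library. The gene annotation is not given in the sources used here. The deposited matrices hold whole-number counts of UMIs per gene and barcode, and the deposited antibody matrices whole-number counts per antibody and barcode, without normalization. Of 30398 gene IDs in the files, 28613 match GENCODE release 29 (GRCh38) with their version and 30296 without it, and coordinates come from that release.

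Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. In donors 1 and 2 that left 4102 and 4397 DZ cells, 5083 and 6059 LZ cells and 4793 and 3625 total GC cells, and 4344 and 4571 cells in captures a and b of donor 3. UMIs in the cells kept ran from 22875709 (DZ 1) to 34743271 (LZ 2) in the sorted set, with 47688713 in a and 52191092 in b. Median UMIs per cell were 4401 and 5895 in DZ, 4580 and 4778 in LZ, 4502 and 5854 in total GC and 8414.5 and 8773 in a and b. The median antibody count per barcode was 61 and 71. XIST, TSIX and genes of the Y chromosome were left out of every step. They were matched by gene ID without version, so genes in the regions that X and Y share were left out too. Among list members and markers these include P2RY8 and IL3RA. Libraries of 1 group were compared for duplication; they differed beyond sampling noise, with a chi-square per degree of freedom of 33.2 in DZ, 37.8 in LZ and 52.9 in total GC. Scrublet, the doublet caller chosen beforehand, marked 0 or 1 cell per library and so did not work. No cells were removed as doublets, and an alternative leaves out the cells at or above the 95% point of the scores of each library. Scores are tied, so more than 5% went: 211 (total GC 2) to 371 cells (LZ 2) per library, with 217 of 4102 in DZ 1 and 360 of 5083 in LZ 1.

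UMI counts were summed per library over the cells kept and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, a low-count filter by group, a quasi-likelihood fit of the 6 sorted libraries with 3 groups (3 residual degrees of freedom, or 2 with the donor as a block), and Benjamini-Hochberg adjustment at 0.05. Cells of 1 library are not replicates, and n is the number of libraries. Total GC was tested against the log-scale mean of DZ and LZ. For phase calls each cell was thinned to 2000 UMIs, a number set after the depths were seen, and scored with scanpy 1.11.5 on fixed S and G2M lists. Counts were summed per library and class, and the interaction of zone and class was fitted with a term for each library. With 1 library left out, the lone library of a group is assumed to vary like the other groups. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks only whether a list moves on balance one way. DESeq2 1.42.0 was an alternative; adjusted p-values it gives as missing were kept missing.

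Donors 1 and 2 provide 1 library of each sorted group, so the numbers pair libraries. The deviations of same-numbered libraries from their group means correlated across genes with r = 0.726 for DZ and LZ, 0.757 for DZ and total GC and 0.731 for LZ and total GC. The fit without the donor was fixed as the main one, and the one with it as an alternative, which called 7019 genes between DZ and LZ. Between donors, the DZ to LZ log2 differences of 6979 genes with at least 10 CPM had r = 0.952 and rho = 0.926, across genes that are not independent.

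For cell classes, the sorted libraries and donor 3 were clustered apart on log-scaled counts of all UMIs, not on thinned counts. The settings were 2000 variable genes, 30 components, 15 neighbours and Leiden at resolution 1.0 with leidenalg 0.10.2. A cluster was called like 1 of 12 classes when at least 3 of its fixed markers were raised by log2 0.5 and their mean log2 was at least 1.0. Clusters with markers of several classes were split once at resolution 0.5. This rule replaced a first one (mean of at least 0.5, no splitting) after its classes had been seen, and both are given. Clustering of donor 3 used RNA only. Antibody gates took the upper and lower 0.333 of cells by CXCR4 and CD83 counts within each capture, over genes with at least 10 CPM and a pseudocount of 1 CPM. Sets high for 1 antibody are the cells at or above the 90% point of its counts and low sets those at or below the median; ties made them 441 to 617 and 2182 to 2512 cells. Shares have exact binomial intervals at 95%.

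The groups, tests, gene lists, markers, other settings to try and the rule for named genes were fixed before the data were examined. The rule takes the 10 genes each way with the largest fold change between DZ and LZ among called genes with the same direction in both donors and at least 50 CPM. Immunoglobulin, T cell receptor, mitochondrial, ribosomal protein and clone-named genes are left out. It takes 8 each way for total GC and for the antibody gates, 5 each way for each phase class and the interaction, and 5 higher and 3 lower for each antibody. It adds CXCR4, CD83, CD86, CD40, MYC, BCL6, PRDM1, MKI67 and CCR6, and up to 4 called members of each list described. Some genes that the rule takes are not reported here. Where a list had 5 or fewer called members, HMGCS1, TNFRSF17, CD82, LTB, PARP1, ELL3, SPIB, EBF1, S1PR4, GNAI2 and RGS16 were named outside the rule, after their values were seen. The genes of the total GC comparison come from the blocked fit, a choice made after the data were seen. The 30 lists cover DZ and LZ markers, S and G2M phase, NF-kB targets, MYC and ribosome biogenesis, immediate early response, MHC class II presentation, hypermutation and repair, plasmablast, memory B cell, GC regulators, oxidative phosphorylation, glycolysis, cholesterol synthesis, interferon response, heat shock, immunoglobulin constant regions, T cell help, apoptosis, migration, and other cell types (T, follicular helper T, NK, myeloid, plasmacytoid dendritic, naive B, stromal, epithelial and erythroid).

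Each fit was tested on simulated data drawn from the real means with 200 changed genes. Except for the interaction, the means were those of each donor and the spread came from the blocked fit. A gain with the block was thus built in. For total GC no difference between DZ and LZ was simulated. Between DZ and LZ (15319 genes) the fit without a block recovered 1.0% of 2-fold and 41.8% of 4-fold changes with 0 false calls, and with the block 77.0% and 98.0%, with 11 unchanged genes (5.98% of calls) called. For total GC (15334 genes) these were 16.0% and 45.9% with 0 false calls, and with the block 80.0% and 93.9% with 11 unchanged genes (6.01%) called. In G1-called cells (13116 genes) 3.33% and 38.4% were recovered and in cells called S or G2/M (14247 genes) 6.25% and 37.6%, both with 0 false calls. The interaction fit (14406 genes) recovered 60.6% and 72.0%, with 8 unchanged genes (6.06%) called. The list test on the same 15319 genes called a raised list of 20 genes and 0 of 30 random lists. Random lists were not built from genes that vary together, as the genes of a real list can. That result therefore does not test the preset correlation on which the list calls rest. For the antibody gates only the CPM ratio was tested (7229 genes), on simulated sums without cells, antibody counts or gating. It gave the right sign for 100% of changed genes, with a median estimate over truth of 0.976 at 2-fold and 0.961 at 4-fold. Alternatives were other scaling, tests, filters, depths, cell filters, clusterings and gates, and each replicate left out. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.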

Results

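Germinal centre (GC) B cells of human tonsil were profiled by droplet single-cell RNA sequencing in 10 libraries of 5 groups. Donors 1 and 2 each gave dark zone (DZ) cells sorted as high for CXCR4 and low for CD83, light zone (LZ) cells sorted the opposite way, and total GC cells taken with the shared gate (negative for CD3 and IgD, positive for CD38). Donor 3 gave total GC cells in 2 captures, a and b, each read as an RNA library and a library of tags from 6 antibodies (CXCR4, CD83, CD9, CCR6, CD69 and CD44). The DZ libraries of donors 1 and 2 held 4103 and 4399 barcodes with 22902045 and 32492462 unique molecular identifiers (UMIs). The LZ libraries held 5085 and 6061 barcodes with 28940758 and 34782796 UMIs, and the total GC libraries 4798 and 3631 barcodes with 27996638 and 28684028 UMIs. A library is named by its group and donor (DZ 1, LZ 2). Captures a and b held 4513 and 4777 barcodes with 48362991 and 53012528 UMIs, and 400849 and 539908 antibody counts. Levels are in CPM after TMM scaling, with SD over n = 2 libraries for levels and SE for log2 fold changes. The SE is the absolute log2 fold change over the square root of its F statistic. Levels of CCL22, TRAC, TRBC2, CD3D, CD3E, GNLY, LYZ, CST3, GZMB and JCHAIN, and all levels in donor 3, are in CPM without TMM scaling. Intervals on shares cover counting error only.

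The first comparison asked which transcripts separate the DZ, where GC B cells divide and mutate their antibody genes, from the LZ, where they are selected on antigen and T cell help. DZ cells held more of PLK1, a mitotic kinase, at 144 ± 14.9 CPM against 16 ± 0.934 CPM in LZ cells (SD, n = 2 each), a 9.01-fold difference (log2 3.17 ± 0.29, adjusted p = 0.00315, edgeR). LZ cells held more of EBI3, a cytokine subunit, at 156 ± 41.4 CPM against 1.34 ± 0.389 CPM (log2 -6.88 ± 0.43, 118-fold, adjusted p = 0.00173). Of genes in lists fixed in advance, 53 of 54 G2M-phase genes were higher in DZ cells, and 16 of 18 NF-kB targets and 17 of 22 MYC and ribosome biogenesis genes in LZ cells, though 0 lists were called with an estimated correlation. In all, 2872 of 15624 genes were called, 1347 higher in DZ and 1525 higher in LZ, and all 2872 had the same direction in both donors. The calls were made on these same donors and favour genes with 1 direction, so this is not a separate replication.

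Among the DZ genes, CXCR4, the chemokine receptor of the sort, stood at 499 ± 22.8 CPM against 55.6 ± 38.5 CPM (8.98-fold, log2 3.17 ± 0.50, adjusted p = 0.0127, with log2 differences of 2.62 and 4.04 in donors 1 and 2). SUGCT, a mitochondrial CoA transferase, was 8.16-fold higher (log2 3.03 ± 0.12, 244 against 29.9 CPM). CDC20 and UBE2C, parts of the machinery that ends mitosis, were 7.42-fold and 6.37-fold higher. The cyclin gene CCNB2 was 6.72-fold higher, the spindle gene HMMR 6.57-fold, and the kinetochore genes CENPF and CENPE stood at log2 2.63 and 2.62. These genes had adjusted p-values of 0.00127 to 0.0127.

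Among the LZ genes, MIR155HG, a microRNA host transcript, was 26.4-fold higher (log2 -4.72 ± 0.45, 201 against 7.63 CPM). The survival gene BCL2A1 stood at 421 ± 69.6 CPM in LZ cells and 22.8 ± 0.829 CPM in DZ cells (18.5-fold, log2 -4.21 ± 0.21, adjusted p = 0.00138). DUSP2, a MAP kinase phosphatase, was 14.6-fold higher (log2 -3.87 ± 0.33). CD83, the other marker of the sort, stood at 744 ± 11.4 CPM against 68.8 ± 8.52 CPM (10.8-fold, log2 -3.43 ± 0.16, adjusted p = 0.00127). FCRL5, an Fc receptor-like gene, was 9.10-fold higher, the adaptor TRAF4 6.67-fold, PPAN, a ribosome biogenesis gene, 6.61-fold, the class II gene HLA-DQB1 5.23-fold (309 against 1616 CPM) and DHRS9, a retinol dehydrogenase, 5.18-fold. The chemokine CCL22 had 0 counts in the DZ libraries and 908 in the LZ libraries (14.3 CPM), at least 263-fold higher in LZ with 3 counts over the group as the floor. CXCR4 and CD83 defined the gates, so their differences are not independent of the sort.

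Of other genes named in advance, the costimulatory receptor gene CD40 was 2.31-fold higher in LZ cells (log2 -1.21 ± 0.14, adjusted p = 0.00572), the growth regulator MYC 6.24-fold (83.0 against 13.3 CPM, adjusted p = 0.00919), the plasma cell regulator PRDM1 11.1-fold (26.1 against 2.39 CPM, adjusted p = 0.00718) and the chemokine receptor CCR6 6.36-fold (adjusted p = 0.00394). MKI67, a proliferation marker, was 3.52-fold higher in DZ cells (209 against 59.4 CPM, adjusted p = 0.00274). The costimulatory ligand CD86 (log2 -0.84 ± 0.41, adjusted p = 0.22) and the GC regulator BCL6 (log2 0.86 ± 0.39, adjusted p = 0.199) did not pass. In the annotation of GRCh38, CXCR4 (ENSG00000121966.6) lies on chromosome 2 from 136114349 to 136118165. EBI3 (ENSG00000105246.5) lies on chromosome 19 from 4229498 to 4237531 and CD83 (ENSG00000112149.9) on chromosome 6 from 14117256 to 14136918.

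**Figure D1:**
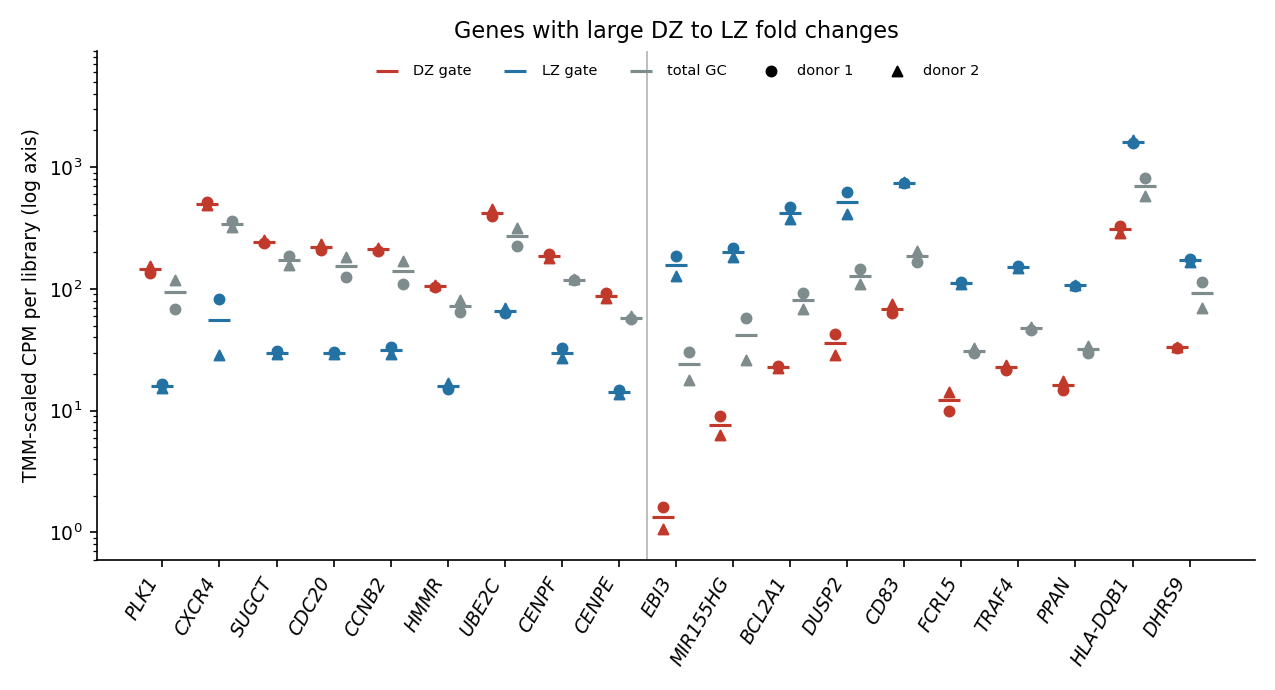
Level of genes with large zone differences in TMM-scaled CPM per library on a log axis, for DZ (red), LZ (blue) and total GC (grey) libraries; circles are donor 1, triangles donor 2 and dashes group means. CXCR4 averages 499 CPM in DZ and 55.6 CPM in LZ, and EBI3 1.34 CPM in DZ and 156 CPM in LZ.

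The 30 gene lists were fixed in advance and tested with camera at a preset correlation, with a second adjusted p from an estimated correlation. Of 54 G2M-phase genes, 53 rose in DZ cells and 54 did adjusted over the list alone, with a median log2 of 2.05 (adjusted p = 2.05e-59, or adjusted p = 0.139 with an estimated correlation). Examples are PSRC1 (3.72), GAS2L3 (3.27) and NEK2 (2.92), which act on the mitotic spindle. Of 43 S-phase genes, 17 rose in DZ cells and 25 did adjusted over the list alone, among them the nucleotide synthesis genes RRM2 (1.62) and TYMS (1.49) and the primase PRIM1 (1.55). That list had a median of 0.75 (adjusted p = 1.49e-12, or adjusted p = 0.298 with an estimated correlation). Of 8 DZ markers, 6 were higher in DZ cells and 8 adjusted over the list alone (median 2.34; adjusted p = 2.36e-13, or adjusted p = 0.0701 with an estimated correlation), with BACH2, a transcriptional repressor, at 2.42. Of 12 LZ markers, 10 were lower in DZ cells and 11 adjusted over the list alone (median -2.70; adjusted p = 1.13e-18, or adjusted p = 0.126 with an estimated correlation), with the receptor SLAMF1 at -3.63. These marker lists hold the sort genes CXCR4 and CD83.

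NF-kB targets were higher in LZ cells for 16 of 18 genes and for 18 adjusted over the list alone, including the chemokines CCL4 (-4.17) and CCL3 (-3.92) (median -2.09; adjusted p = 3.62e-20, or adjusted p = 0.0701 with an estimated correlation). MYC and ribosome biogenesis genes were higher in LZ cells for 17 of 22 genes and for 19 adjusted over the list alone. Examples are the cyclin CCND2 (-4.96), MYBBP1A (-2.31), which acts in the nucleolus, and the polyamine enzyme SRM (-2.07), and the list had a median of -1.13 (adjusted p = 1.04e-16, or adjusted p = 0.175 with an estimated correlation). Of 15 immediate early genes, 7 were higher in LZ cells and 10 adjusted over the list alone, led by the transcription factors EGR3 (-4.43), EGR2 (-4.33) and NR4A1 (-3.23) (adjusted p = 6.02e-09, or adjusted p = 0.175 with an estimated correlation). Of 14 genes of MHC class II presentation, 6 were higher in LZ cells and 9 adjusted over the list alone (adjusted p = 2.22e-07, or adjusted p = 0.312 with an estimated correlation). They included the class II regulator CIITA (-1.86), the lysosomal reductase IFI30 (-1.86) and HLA-DPA1 (-1.29).

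Genes of T cell help and costimulation were higher in LZ cells for 9 of 14 genes, also 9 adjusted over the list alone, and IL4R was higher in DZ cells (1.15) (adjusted p = 1.36e-06, or adjusted p = 0.126 with an estimated correlation). The LZ genes included TNFRSF13B (-3.06), the adhesion gene ICAM1 (-2.58) and the death receptor FAS (-1.43). Of 14 apoptosis genes, 7 were higher in LZ cells and 7 adjusted over the list alone (adjusted p = 2.90e-04, or adjusted p = 0.139 with an estimated correlation). BCL2A1, BCL2 (-1.92) and BCL2L1 (-1.59) among them encode proteins that oppose cell death. Of 11 cholesterol synthesis genes, 5 were higher in LZ cells and 7 adjusted over the list alone (adjusted p = 0.00141, or adjusted p = 0.145 with an estimated correlation). Those that passed over all genes were LSS (-1.97), DHCR7 (-1.36), INSIG1 (-1.06), SQLE (-0.92) and HMGCS1. Of 16 plasmablast genes, 8 were higher in LZ cells, led by PRDM1, IRF4 (-3.43) and the protein folding genes HSP90B1 (-1.74) and FKBP11 (-1.42). Plasmablast-like cells, named from these RNA data, made up 0.341% and 0.546% of DZ cells and 5.86% and 9.19% of LZ cells in donors 1 and 2. In LZ cells 96.98% and 97.85% of them lay in a cluster led by FRZB and PRDM1. In DZ cells 78.57% and 79.17% of them (11 and 19 cells) lay in a cluster led by FKBP11 and MZB1, which held 9 and 12 LZ cells. The higher share in LZ cells thus came from the cluster led by FRZB and PRDM1. Without plasmablast-like cells and other cell types the log2 differences were -3.51 for PRDM1, -4.45 for IRF4, -1.84 for HSP90B1 and -1.87 for FKBP11. TNFRSF17, which was named after its value was seen, was higher in DZ cells. Adjusted over the list alone, 8 were higher in LZ and 4 in DZ (adjusted p = 0.00406, or adjusted p = 0.317 with an estimated correlation). Of 14 memory B cell genes, TNFRSF13B, CCR6, CD44 (-2.63), BCL2 and CD82 were higher in LZ cells and LTB in DZ cells. Adjusted over the list alone, 7 and 1 passed (adjusted p = 0.0136, or adjusted p = 0.175 with an estimated correlation).

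**Figure D2:**
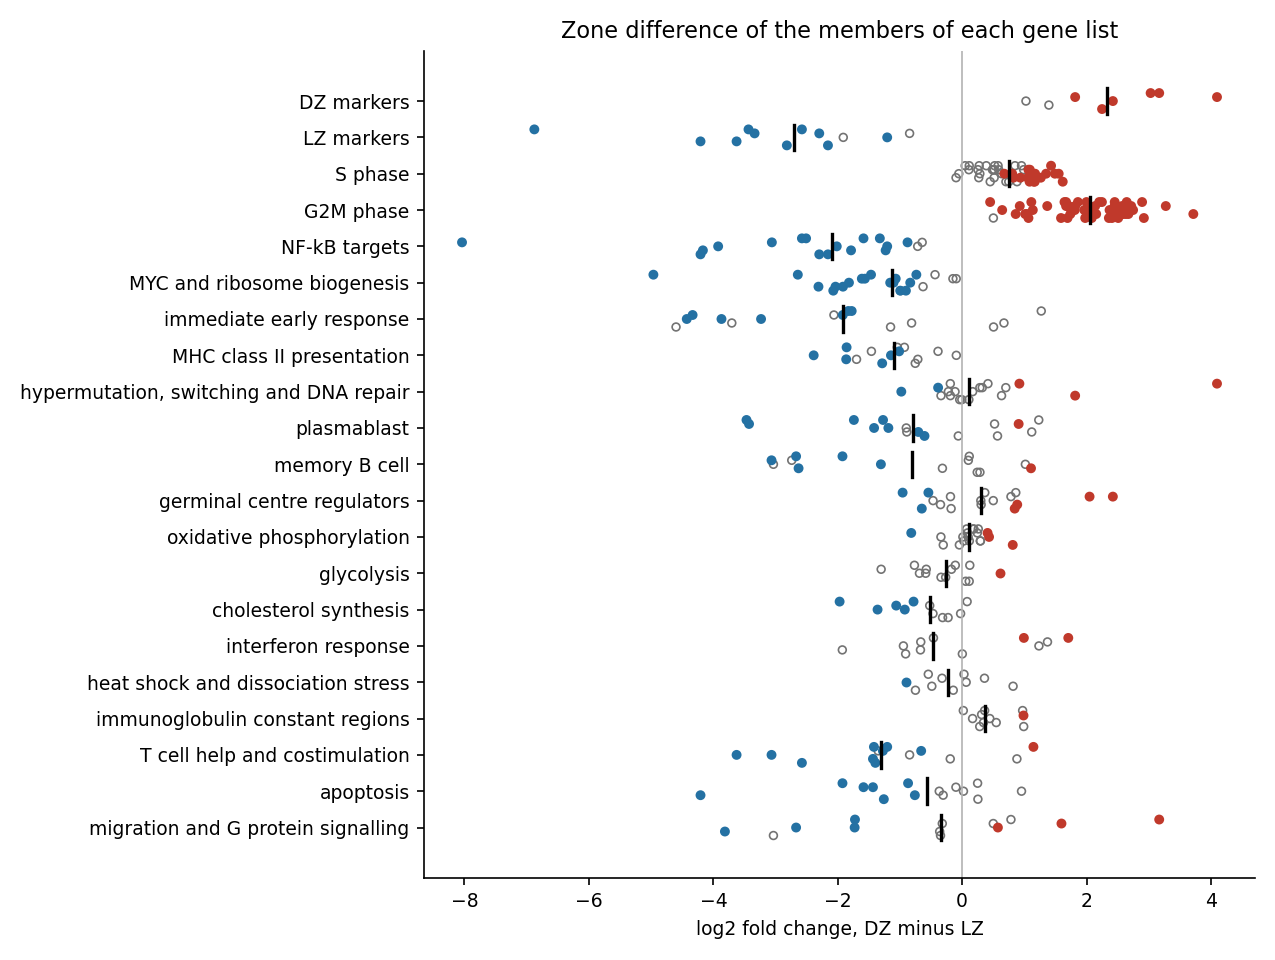
Zone difference (log2 fold change, DZ minus LZ) of each tested member of 21 gene lists; filled points passed the test over all genes, open points did not, and black bars mark list medians. The G2M-phase list lies to the right (median 2.05) and the LZ marker list to the left (median -2.70); CCL22 is drawn at its bound.

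Another 8 lists of B cell genes were not called as sets. Of 19 genes of hypermutation, switching and repair, the repair polymerase POLH (1.82) and the ligase LIG1 (0.92) were among those higher in DZ cells and APEX1 (-0.98) and PARP1 were higher in LZ cells. The counts were 3 and 2 adjusted over the list alone (adjusted p = 0.165; 0.490 with an estimated correlation). Of 17 GC regulators, BACH2, GCSAM (2.05), POU2AF1 (0.89) and ELL3 were higher in DZ cells and SERPINA9 (-0.96), SPIB and EBF1 in LZ cells. The counts were 6 and 3 adjusted over the list alone (adjusted p = 0.0795; 0.307 with an estimated correlation). Of 13 migration genes, CXCR4, S1PR4 and GNAI2 were higher in DZ cells and CCR7 (-3.81), CCR6, RGS1 (-1.73) and RGS16 in LZ cells. They numbered 4 and 5 adjusted over the list alone (adjusted p = 0.165; 0.312 with an estimated correlation). Of 11 immunoglobulin constant genes, IGHA1 (0.98) was higher in DZ cells, a call lost without plasmablast-like cells and other cell types (log2 0.553, adjusted p = 0.0767), and 0 passed adjusted over the list alone (adjusted p = 0.0628; 0.312 with an estimated correlation). Of 19 oxidative phosphorylation genes, COX8A (0.81), COX6A1 (0.43) and UQCRH (0.41) were higher in DZ cells and ATP5G1 (-0.82) in LZ cells. They numbered 5 and 1 adjusted over the list alone (adjusted p = 0.228; 0.757 with an estimated correlation). Of 13 glycolysis genes GAPDH (0.61) was higher in DZ cells and 0 passed adjusted over the list alone (adjusted p = 0.269; 0.80 with an estimated correlation). Of 10 heat shock genes HSPE1 (-0.90) was higher in LZ cells, also adjusted over the list alone (adjusted p = 0.260; 0.757 with an estimated correlation). Of 11 interferon genes, ISG20 (1.71) and MX1 (0.99) were higher in DZ cells, also adjusted over the list alone. The list's median (-0.46) and mean (-0.03) were negative while the direction of its test was up (adjusted p = 0.939; 0.95 with an estimated correlation).

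Few markers of other cell types were called between the gates. Of 7 naive B cell genes, CCR7, FCER2 (-2.96) and CD72 (-1.42) were higher in LZ cells and IL4R in DZ cells (adjusted p = 0.0795; 0.298 with an estimated correlation). The inhibitory receptor PDCD1 (-3.89) was higher in LZ cells among 4 follicular helper T cell genes (adjusted p = 0.329), and FCN1 (-2.19) among 8 myeloid genes (adjusted p = 0.986). No gene was called by edgeR among 7 T cell genes (adjusted p = 0.577), 3 NK genes (adjusted p = 0.472), 4 plasmacytoid dendritic genes (adjusted p = 0.986, median -0.07 and mean 0.46). None was called among the 1 stromal, 2 epithelial and 2 erythroid genes that could be tested, in lists too short for a set test.

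The replicate numbers pair libraries of 1 donor, and with the donor as a block edgeR called 7019 of 15624 genes in place of 2872, CD86 and BCL6 among them. Under that block 36 S-phase, 7 immunoglobulin and 1 T cell genes were higher in DZ cells. Higher in LZ cells were 11 immediate early, 13 MHC class II, 8 cholesterol, 4 heat shock, 2 follicular helper and 2 NK genes, and 1 epithelial gene was higher in DZ cells. Higher in DZ and in LZ were 4 and 10 plasmablast, 7 and 3 hypermutation, 10 and 5 GC regulator, 7 and 3 oxidative phosphorylation, 1 and 6 glycolysis, 3 and 6 interferon, 5 and 7 migration and 2 and 1 plasmacytoid dendritic genes. Counts near the share of all genes called, such as 4 of 10 heat shock and 2 of 4 follicular helper genes, do not set a list apart. As sets, with the block and the preset correlation, hypermutation (adjusted p = 0.0245), GC regulators (0.0132), immunoglobulin (0.0245), migration (0.0493) and naive B cell genes (0.00695) were also called. With the block and an estimated correlation 0 lists were. Leaving out 1 library left 809 calls without DZ 1, 892 without DZ 2, 751 without LZ 1 and 893 without LZ 2. Genes named outside the rule were not followed in these refits. Of the 81 called genes that the rule takes, 52 were called in every such refit. The other 29 lost the call in at least 1 refit: CXCR4, CCND2 and TNFRSF13B (without DZ 1 or DZ 2), CCL3 and HLA-DPA1 (without LZ 1), IRF4 and ATP5G1 (DZ 1 or LZ 2), MX1 (DZ 2 or LZ 1) and GAS2L3 (DZ 2 or LZ 2). Without 3 or more of the 4 gated libraries in turn, these were BCL2, COX6A1, DHCR7, FCN1, FKBP11, GAPDH, HSPE1, IGHA1, LIG1, LSS, RRM2, TYMS, UQCRH, CCL4, FCER2, HSP90B1, APEX1, CIITA, INSIG1 and POU2AF1. Values of HLA-DQB1 and the other HLA genes, CCL3 and CCL4, and PPAN, which overlaps a neighbouring gene, are uncertain because the counting could split or share their reads.

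The second comparison asked what total GC cells hold that the 2 gates together do not. Without a donor term edgeR called 0 of 15624 genes, with 636 at an unadjusted p under 0.05. DESeq2 called 84, of which 83 were higher in total GC. With the donor as a block, which removes the difference between donors, edgeR called 369 genes, 337 higher in total GC and 32 lower. The genes named here come from that fit because the first called none. Only 67 of the 337 stood above both gates in both donors, and the median log2 of the 337 fell from 0.679 to 0.2827 against the arithmetic mean of the gates. CXCR4 was 2.12-fold higher in total GC than in the log-scale mean of the gates (log2 1.08, adjusted p = 0.0309) and SUGCT 2.0-fold (log2 1.0), but at 339 and 171 CPM both lay below DZ cells. MZB1, a chaperone of antibody secretion, was 1.82-fold higher (log2 0.86 ± 0.06, adjusted p = 0.000225), at 318 CPM in total GC, 212 in DZ and 143 in LZ cells, and by log2 0.30 ± 0.06 without plasmablast-like cells and other cell types.

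Further genes higher in total GC were the mitotic genes PLK1 (log2 0.93), CDC20 (0.92) and HMMR (0.81). The lower genes differed less: AMD1 (-0.39) and SMS (-0.36) of polyamine synthesis, the ribosome biogenesis genes PPAN (-0.38) and DKC1 (-0.38), the kinase PIM3 (-0.37), the deubiquitinase OTULIN (-0.36), the NF-kB subunit REL (-0.35) and NIPA2 (-0.35). In fits without the block, leaving out total GC 1 or total GC 2 gave 1.31 or 0.507 for PLK1, -0.597 or -0.208 for AMD1, -0.245 or -0.517 for DKC1, -0.633 or -0.117 for OTULIN and -0.597 or -0.118 for REL. By list and with the block, 10 of 16 plasmablast genes were higher and 14 adjusted over the list alone (adjusted p = 3.33e-30, or adjusted p = 0.0779 with an estimated correlation). For immunoglobulin constant genes these counts were 8 and 9 of 11 (adjusted p = 2.05e-32, or adjusted p = 0.0779 with an estimated correlation), for DZ markers 6 and 7 of 8 (adjusted p = 2.91e-29, or adjusted p = 0.0779 with an estimated correlation) and for G2M genes 38 and 47 of 54 (adjusted p = 1.65e-78, or adjusted p = 0.275 with an estimated correlation). Without the block, 6 plasmablast, 7 immunoglobulin, 5 DZ marker and 36 G2M genes passed adjusted over the list alone. With the block, leaving out total GC 1 or total GC 2 gave a median log2 of 0.709 or 0.564 for plasmablast genes and 0.722 or 0.426 for G2M genes. These medians were 0.504 or 0.743 for immunoglobulin constant genes and 0.534 or 0.653 for DZ markers. Among other cell types and with the block, 2 myeloid genes, 1 T cell gene, 1 NK gene and 1 naive B cell gene were called higher in total GC. Another 13 lists were called as sets with the preset correlation but not with an estimated one (adjusted p-values of 0.275 to 0.484). Of these the myeloid (adjusted p = 1.13e-05), T cell (3.14e-05), NK (0.00175), plasmacytoid dendritic (0.00613), S-phase (9.93e-08), GC regulator (0.00217), hypermutation (0.00326) and interferon (0.00597) lists tested up. MYC and ribosome biogenesis (3.13e-10), NF-kB (3.14e-05), LZ marker (4.76e-05), apoptosis (0.00126) and T cell help (0.00311) lists tested down. Yet 3 NF-kB genes were called higher and 3 lower, with a mean log2 of 0.159, and 1 LZ marker and 1 T cell help gene were called each way. Without total GC 1 the myeloid (adjusted p = 0.905), NK (0.131), plasmacytoid dendritic (0.141), GC regulator (0.366) and interferon (0.366) lists were not called. Without total GC 2 the S-phase (0.422), hypermutation (0.383) and T cell help (0.159) lists were not. The myeloid genes LYZ and CST3 stood at 22.8 and 22.4 CPM in total GC 1 and at 0.908 and 1.01 CPM in total GC 2. Without the block the NK (0.0712), plasmacytoid dendritic (0.0517) and hypermutation (0.0504) lists did not pass.

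The third comparison asked which zone differences hold apart from the cell cycle. At 2000 UMIs per cell, 64.5% ± 4.85 of DZ cells and 25.3% ± 1.26 of LZ cells were called S or G2/M from the fixed S and G2M lists (SD, n = 2), a difference of 39.2 points (43.5 in donor 1 and 34.9 in donor 2; exact permutation p = 0.33, two-sided, the smallest that 2 against 2 allows). The shares were 67.9% and 61.1% in DZ, 24.4% and 26.2% in LZ, 41.6% and 51.9% in total GC and 48.0% and 48.6% in captures a and b. On all UMIs the means were 61.8% in DZ and 22.4% in LZ. In all 111 cells of DZ 1, 14 of a and 13 of b were too shallow to be thinned. These are calls from RNA, which free RNA in the droplets can enter, and they do not by themselves show division.

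In G1-called cells and in cells called S or G2/M, SUGCT was 12.8-fold and 9.65-fold higher in DZ cells and CXCR4 12.1-fold and 7.44-fold. The LZ genes MIR155HG (29.6-fold and 23.6-fold), BCL2A1 (11.6-fold and 17.2-fold), DUSP2 (log2 -3.41 and -3.70) and CD83 (7.90-fold and 9.62-fold) were higher in LZ cells in both classes. In G1-called cells the largest differences also held LGALS1, a lectin gene (log2 2.75), and EBI3 (136-fold higher in LZ). In cells called S or G2/M they held BACH2 (6.46-fold) and the transcription factor BATF (8.60-fold higher in LZ). In all, 2054 of 13186 genes were called in G1-called cells (970 higher in DZ, 1084 in LZ) and 2502 of 14174 in the others (1158 and 1344).

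Of 12999 genes tested in both classes, 647 were called higher in DZ in both, where independent lists of 964 and 1119 genes would share 83.0, and 838 higher in LZ, where lists of 1083 and 1327 would share 111. Both classes come from the same libraries, so part of the excess may follow from the shared samples. In G1-called cells 12 NF-kB targets and 17 MYC and ribosome biogenesis genes were higher in LZ cells, and in cells called S or G2/M 15 and 19. The S and G2M lists set the phase calls, so their genes are not read as zone differences within the classes. G1-called cells still differed in them: 19 of 51 G2M genes were called higher in DZ cells and 3 lower (median log2 0.833). Of 42 S-phase genes 6 were higher and 1 lower (median 0.232). The G1 class thus did not remove every cell cycle difference between the zones. With the donor as a block 5262 genes were called in G1-called cells and 6096 in the others. Without 1 gated library the count in G1-called cells was 394 (LZ 1), 469 (DZ 1), 613 (DZ 2) or 614 (LZ 2). In the others it was 682 (LZ 1), 763 (LZ 2), 835 (DZ 2) or 866 (DZ 1). The call of CXCR4 in cells called S or G2/M was lost without DZ 1 or DZ 2. Without a low-count filter 3280 genes were called in G1-called cells.

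A test of the zone by phase interaction called 1258 of 14389 genes, 624 with a DZ to LZ difference that was more positive in cells called S or G2/M and 634 with one that was more negative. ARL6IP1, an endoplasmic reticulum gene, moved by log2 1.93 ± 0.08 (adjusted p = 8.43e-17), from -0.50 in G1-called cells to 1.45, and the importin gene KPNA2 by 1.91, from -0.82 to 1.10. UBALD2 moved by 1.64, the ubiquitin enzyme gene UBE2S by 1.48 and the tubulin gene TUBB4B by 1.44. In the other direction the replication factor gene PCLAF moved by -1.82, from 2.64 to 0.83, BIRC5, a gene of mitosis, by -1.62, the meiotic recombination gene MND1 by -1.48 and SP110 by -1.27. XBP1, a regulator of secretion, moved by -1.47, from -0.19 in G1-called cells to -1.66. DESeq2 called 377 genes, and leaving out 1 library left 822 (DZ 1) to 941 (LZ 1) calls. Without a low-count filter the split was 1075 to 393 among 1468 calls, where the median over all genes shifted to 0.16. UBE2S and TUBB4B belong to families whose members share sequence, and TUBB4B and BIRC5 are on the list that set the phase calls. Genes off the lists that vary with the cell cycle may follow the calls as well, which was not tested.

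**Figure D3:**
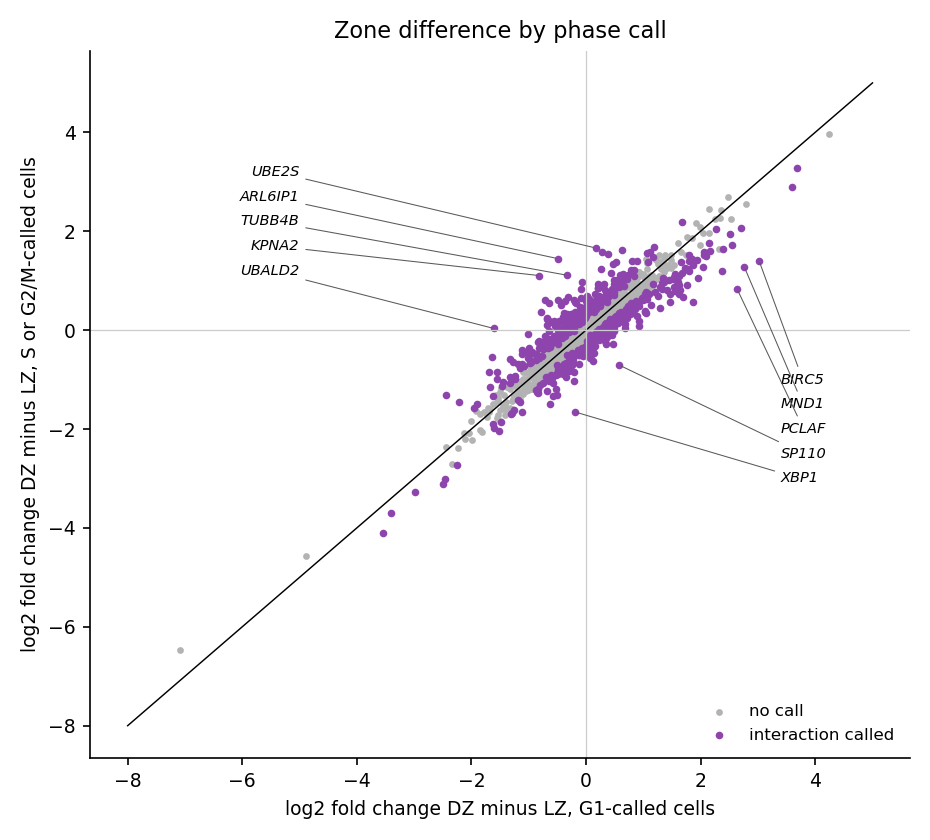
Zone difference (log2 fold change, DZ minus LZ) in G1-called cells on the horizontal axis and in cells called S or G2/M on the vertical axis, for 2379 genes with at least 50 CPM; purple points are the 562 with a called interaction, and the black line marks equal differences. The points scatter about the line, with ARL6IP1 and KPNA2 above it and PCLAF below.

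In total GC, plasmablast-like cells, named by fixed markers such as PRDM1, XBP1 and MZB1, made up 3.09% of cells in donor 1 (148 of 4793, exact binomial 95% interval 2.62 to 3.62%) and 4.25% in donor 2 (154 of 3625, 3.61 to 4.96%). In captures a and b of donor 3 they made up 1.63% (71 cells, 1.28 to 2.06%) and 1.36% (62 cells, 1.04 to 1.74%). Pre-memory-like cells, named by genes such as CCR6, BANK1 and TNFRSF13B, made up 1.90% (91 cells, 1.53 to 2.33%) and 2.48% (90 cells, 2.0 to 3.04%) in donors 1 and 2, and 1.10% (48 cells, 0.816 to 1.46%) and 1.44% (66 cells, 1.12 to 1.83%) in a and b. Kit and donor change together between these sets, so no test was made. In donors 1 and 2, 56.1% and 48.1% of the plasmablast-like cells lay in a cluster led by FRZB and PRDM1 and the rest in one led by FKBP11 and MZB1, whose median UMIs were 9964 and 12047, where the library medians were 4502 and 5854. The FRZB and PRDM1 cluster had median UMIs of 4269 and 4922.5. LZ libraries held more cells of that cluster. Yet, without TMM scaling, JCHAIN stood at 176 and 323 CPM in LZ and 423 and 651 CPM in DZ libraries. MZB1 stood at 130 and 156 CPM in LZ and 196 and 223 CPM in DZ. XBP1 went the other way (85.7 and 98.7 CPM in LZ, 40.3 and 40.2 CPM in DZ). Whether that cluster holds secreting cells was not tested. Without the cells of highest doublet scores the shares were 3.16% and 4.28% in donors 1 and 2 and 1.64% and 1.36% in a and b.

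DZ-like cells made up 12.7% and 14.2% of total GC in donors 1 and 2 and LZ-like cells 10.8% and 6.51%, while 70.0% and 72.0% stayed unnamed. Plasmacytoid-dendritic-like cells made up 0.230% and 0.055%, and myeloid-like cells 0.167% in donor 1 and 0 cells in donor 2. A cluster of 160 cells in the 6 libraries was named NK-like but mixed NK and T cell genes (GNLY, NKG7, CD3D) with pre-memory genes (PLAC8, TNFRSF13B). It was left unnamed at other resolutions, and total GC 2 held 5 UMIs of GNLY in all, so no share of NK cells is given. No cluster was named T-cell-like, which sets no limit on T cells while most cells stayed unnamed. The threshold that names a cluster was set after the data were seen. A lower one would add 17.5% and 22.8% of total GC cells to the DZ-like class in donors 1 and 2. In a and b it would add 17.9% and 18.1% to a naive-B-like class and 1.08% and 0.897% to the plasmablast-like class. The pre-memory-like share also depended on the clustering: its mean over donors 1 and 2 was 2.19%, and 0 or 0.138% at other resolutions.

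The fourth comparison asked whether antibody counts in donor 3 separate the same transcripts as the sort did in donors 1 and 2. Cells among the upper 0.333 for CXCR4 antibody and the lower 0.333 for CD83 antibody (633 in a, 736 in b) were set against the reverse (648 and 914). No test was made, since both captures come from 1 donor. PLK1 was higher in the CXCR4-high gate by log2 2.26, UBE2C by 2.12, CDC20, CENPF and CCNB2 by 2.11 each, CXCR4 by 2.09 and the pseudogene ANKRD36BP2 by 2.42 (mean of a and b). BCL2A1 (-3.34), MIR155HG (-3.16), DUSP2 (-3.06), FCRL5 (-2.58), CD83 (-2.43), TRAF4 (-2.13) and PARP14 (-2.09) were higher in the CD83-high gate, as was LMO2, a GC transcription factor (-2.17), which did not pass between the sorted gates (log2 -1.91, adjusted p = 0.0611).

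Of 1928 genes called between the sorted gates, 99.0% in a and 98.2% in b had the same sign between the antibody gates, and 99.1% on their mean. Of genes that were not called, 78.5% did. Across 7217 genes, which are not independent replicates, Pearson r was 0.921 and Spearman rho 0.878. The antibody-gate differences were smaller, with a slope on the sorted differences of 0.645 over called genes. Cells called S or G2/M made up 60.7% and 63.6% of the CXCR4-high gate and 29.6% and 34.1% of the CD83-high gate.

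**Figure D4:**
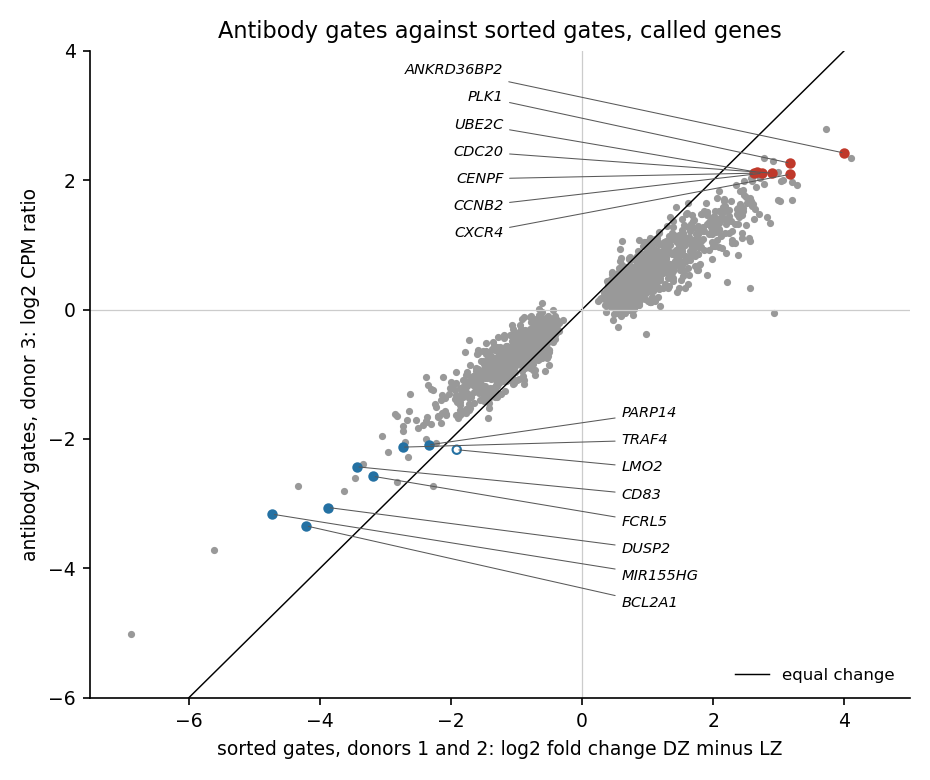
Log2 CPM ratio between antibody gates in donor 3 (vertical axis) against the log2 fold change between sorted gates in donors 1 and 2 (horizontal axis) for the 1928 called genes, with names for genes of large change and at least 50 CPM; the black line marks equal change. PLK1 lies at 2.26 and BCL2A1 at -3.34 on the vertical axis, and LMO2 (hollow) was not called between the sorted gates.

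Antibody counts by RNA class asked whether surface protein follows the classes named from RNA. The markers that name the classes hold the transcripts of CXCR4 (DZ-like), CD83 (LZ-like) and CCR6 and CD44 (pre-memory-like). The levels of those antibodies in those classes are thus partly bound to the naming, while CD9 and CD69 are markers of no class. Library medians were low, so ratios to them are coarse. In a and b they were 8 and 9 counts for CXCR4, 3 and 4 for CD83 and 5 and 6 for CD9. They were 4 and 5 for CCR6, 9 and 11 for CD69 and 15 and 18 for CD44. In DZ-like cells the median CXCR4 antibody count was 1.75 (a) and 1.78 (b) times the library median. In LZ-like cells it was 0.50 and 0.56 times, where CD83 antibody stood at 3.33 and 2.75 times. Plasmablast-like cells had 17.6 and 15 times the library median of the tetraspanin CD9 and 4.47 and 9.17 times that of the adhesion receptor CD44, at median UMIs of 14666 and 15190.5. Pre-memory-like cells had 20.7 and 18.2 times the median of CD44, 4.5 and 4.4 times that of CCR6 and 4.72 and 5.0 times that of the activation marker CD69, at median UMIs of 5503 and 5845. As a share of each cell's 6 antibody counts, which sum to a fixed total, the mean over a and b was 2.80 for CD44, 0.58 for CCR6 and 0.762 for CD69 in pre-memory-like cells, and 4.32 for CD9 and 1.59 for CD44 in plasmablast-like cells.

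**Figure D5:**
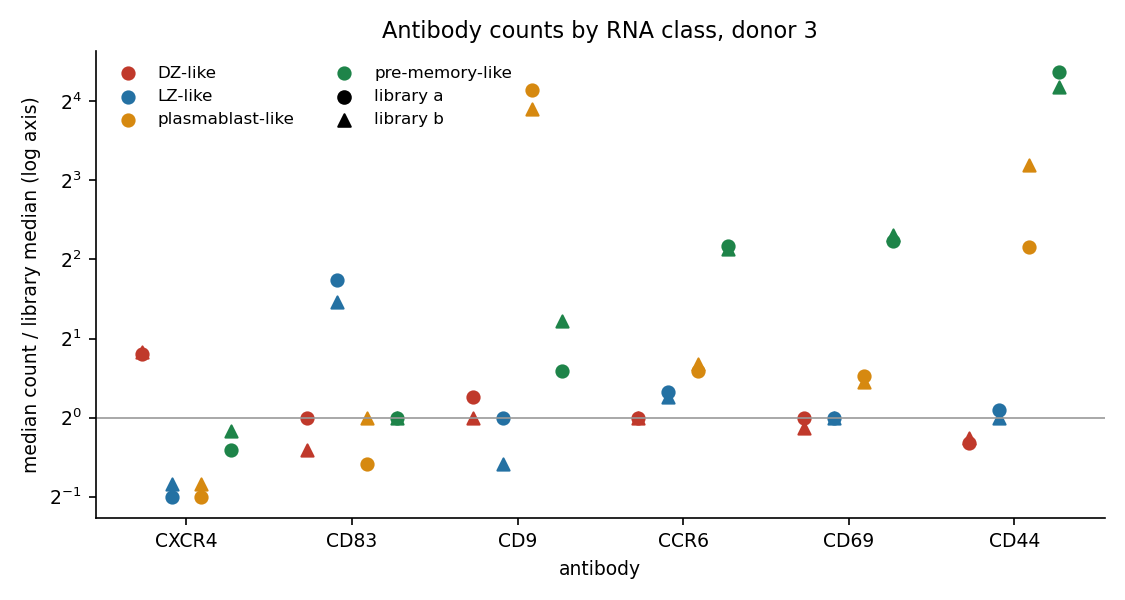
Median antibody count relative to the median of the library on a log axis, for 6 antibodies (horizontal axis) and 4 RNA classes (colours) in captures a (circles) and b (triangles) of donor 3. CD9 is highest in plasmablast-like cells (17.6 and 15) and CD44 in pre-memory-like cells (20.7 and 18.2).

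Antibody count and own transcript were compared across cells, which are not replicates. Spearman rho was 0.50 in both captures for CXCR4, 0.33 for CD83, 0.44 for CD9, 0.25 and 0.23 for CD44, 0.093 and 0.129 for CCR6 and 0.096 and 0.094 for CD69. High sets are the top 10% of cells and low sets the lower 50%, with ties kept, which widened them to at most 617 of 4344 cells (CCR6 in a) and 2512 of 4571 (CD83 in b). Cells in the high set for CXCR4 antibody held more of the mitotic genes UBE2C (log2 1.76), PLK1 (1.69), CENPF (1.64), AURKA (1.64) and CCNB2 (1.62) than cells in the low set, and less of DHRS9 (-2.31), DUSP2 (-2.32) and BCL2A1 (-2.32). For CD83 antibody the high set held more of MIR155HG (3.24), BCL2A1 (3.07), DUSP2 (2.73), CD83 (2.33) and TRAF4 (2.0), and less of SUGCT (-1.99) and ANKRD36BP2 (-2.30). The secretion genes FKBP11 (2.12 and 2.68), HSP90B1 (2.05 and 1.96) and XBP1 (1.92 and 1.78) were higher in cells with most CD9 and most CD44 antibody. Further such genes were SUB1 (1.61) and MZB1 (1.51) for CD9 and DERL3 (1.85) and JCHAIN (1.59) for CD44. Lower genes were SMIM14 (-0.96), PARP14 (-0.97) and HTR3A (-1.10) for CD9 and SMIM14 (-1.15), LTB (-1.42) and SUGCT (-1.50) for CD44.

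Cells in the high set for CCR6 antibody held more of JCHAIN (1.09 in a and 2.18 in b), SSR4 (1.12), XBP1 (1.05), SUB1 (1.03) and TXNIP (0.92) and less of HIST1H3D (-0.38), SLC2A5 (-0.38) and MND1 (-0.39). For CD69 antibody the high set held more of SUB1 (1.34), FCRL5 (1.14), HSP90B1 (1.09), VIM (1.09) and JCHAIN (0.24 in a and 1.8 in b) and less of GINS2 (-0.65), TK1 (-0.66) and TUBB3 (-0.68), genes of replication and the cytoskeleton. Depth differed between these sets of cells: those with most CD44 antibody had median UMIs of 14081 (a) and 15067 (b) against 7378.5 and 7567 in the low set. Cells called S or G2/M made up 64.2% and 64.9% of those with most CXCR4 antibody and 38.4% and 38.0% of the low set.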

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

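The tests of the interaction between zone and phase were written before their results were seen, and the alternatives named here were planned.

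The DZ to LZ difference of 1258 genes differed between G1-called cells and cells called S or G2/M by a test of the difference itself (the interaction term in edgeR), which is why these genes are listed. The largest were ARL6IP1 (log2 1.93), KPNA2 (1.91), UBALD2 (1.64), UBE2S (1.48) and TUBB4B (1.44), and PCLAF (-1.82), BIRC5 (-1.62), MND1 (-1.48), XBP1 (-1.47) and SP110 (-1.27). TUBB4B, BIRC5 and, below, CDC20, UBE2C, MKI67, RRM2, PRIM1, TYMS and CDCA7 are on the S and G2M lists that set the phase calls, so their values are bound to the calls. Genes off the lists that vary with the cell cycle may follow the calls too, which was not tested. G1-called DZ cells still held more of 19 of 51 G2M genes and less of 3. With S and G2/M cells brought to equal numbers in every library, the median ratio of the new to the old interaction was 0.9055 (0.896 to 0.916 on resampled genes, as for the next 2 ranges; 839 of the 1258 genes still called), with every cell thinned to 1 UMI number 0.9464 (0.935 to 0.970; 409 still called, on fewer UMIs), and without the 25% of cells nearest the boundary between phase calls 1.055 (1.045 to 1.064; 826 still called). Each of these argues against its explanation as the whole cause for the genes as a set. The ratios are medians over the called genes, so they do not decide for the single genes named. Equal numbers of S and G2/M cells also leave the mix of cells within a phase as it was, which was not tested. Free RNA in the droplets and a true dependence of zone programmes on phase, which the gates name only for the zone, stay open and were not tested.

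Another 83 named genes had a test of the interaction and 27 were called, 14 with a larger zone difference in cells called S or G2/M and 13 with a smaller one. Among genes higher in LZ cells, the interaction was -0.57 for BCL2A1, -0.36 for DUSP2, -0.29 for CD83, -0.54 for FCRL5, -0.47 for TRAF4, -0.67 for CD40, -0.66 for SLAMF1, -0.39 for IFI30, -1.45 for FKBP11, -1.37 for CD44, -0.29 for SERPINA9, 1.14 for LSS, -0.59 for RGS1 and -2.47 for FCN1. Among genes higher in DZ cells, it was -0.64 for CXCR4, -0.42 for SUGCT, -0.61 for CDC20, -0.85 for UBE2C, -0.71 for MKI67, -1.02 for RRM2, -0.74 for PRIM1, -0.90 for TYMS, -0.49 for CDCA7, 0.84 for POLH, -0.24 for ISG20, -1.26 for IGHA1 and -0.53 for IL4R. Of these 27 and the 10 largest, 20 were called in each of 4 refits with 1 library left out. The call was lost in every refit for CD83 and FCN1, in 3 of them for FCRL5, SLAMF1, ISG20 and CDC20, without DZ 1 or 1 of the LZ libraries for PRIM1, RGS1 and SUGCT, without DZ 2 or 1 of the LZ libraries for LSS, TRAF4, DUSP2 and SERPINA9, without DZ 2 for MKI67 and UBE2C, without LZ 1 for CXCR4 and without LZ 2 for IFI30. Values nearest to 0 that differed by over 1.5 times were -0.311 for CXCR4 and -0.475 for PRIM1 without LZ 1, -0.238 for SUGCT, -0.178 for CD83, -0.316 for FCRL5, -0.175 for IFI30 and -0.0874 for SERPINA9 without LZ 2, -0.235 for RGS1 and -0.130 for ISG20 without DZ 1, and -0.194 for CDC20, -0.0750 for DUSP2, -0.586 for IGHA1, -0.416 for MKI67, -0.423 for SLAMF1 and -0.457 for UBE2C without DZ 2. Those farther from 0 were -0.623 for DUSP2 without DZ 1 and -1.01 for RGS1 without DZ 2.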

How the results depend on the processing

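The alternatives that leave out high doublet scores, change how clusters are named or leave out 1 library in the list tests of total GC were chosen after the data were seen; all others were planned. Of the alternative values of the main results, 127 stayed within their spread or within 1.5 times the main count, 60 moved and 3 reversed. The cause was not tested except where fewer samples or genes entered. Of those of single genes and lists, 2506 stayed, 78 moved, 170 fell short of the threshold, 56 newly passed it and 3 reversed. Part of the values that stayed could not have moved. With 1 of 2 captures or donors left out, the other always lies within the SD around their mean. This holds for class shares of total GC, the rho of antibody and own transcript, and antibody levels by class (30 values among the 2506). The replicate block likewise cannot change the cycling difference. All 6 reversals came with antibody shares and are given below. Most of the 170 were single genes with 1 library left out (89 of 498 between DZ and LZ, 38 of 372 for the interaction) or, for 13, lists with an estimated correlation. With fry 3 further lists were called, and the planned Scrublet alternative could not be run because it marked 0 or 1 cell per library.

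With the donor as a replicate block, calls went from 2872 to 7019 between DZ and LZ, from 0 to 369 for total GC, from 2054 to 5262 in G1-called cells and from 2502 to 6096 in cells called S or G2/M. In simulated data the block also raised the share of changes recovered. Those data held donor differences and a spread taken from the blocked fit, so that gain was built in and does not bear on these calls. Among lists the block newly called 5 and ended no call, and among named genes it newly called CD86 and BCL6 between DZ and LZ and the 16 genes named for total GC. Leaving out 1 library gave 751 to 893 calls between DZ and LZ without a gated library, and 2380 and 2390 without a total GC library. It gave 394 to 614 in G1-called cells and 682 to 866 in cells called S or G2/M without a gated library (1616 to 1618 and 2079 to 2107 without a total GC one), and 822 to 941 for the interaction. These fits hold fewer samples. For total GC it gave 0 calls by edgeR, with 421 to 618 genes at an unadjusted p under 0.05, while DESeq2 called 84 and edgeR without a low-count filter 6. Without that filter G1-called cells had 3280 calls, and DESeq2 called 377 interaction genes, with 7532 adjusted p-values missing. Of the 13 lists called, 0 were with an estimated correlation, and 0 with that and the replicate block.

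The plasmablast-like share of captures a and b went from 1.63% and 1.36% to 2.72% and 2.25% with the lower naming threshold and, with the same values, with the first naming rule. The mean pre-memory-like share of donors 1 and 2 (2.19%) was 0 at resolution 0.5, 0.138% at 2.0, 0.564% with all barcodes, and 0.124% both with mixed clusters left whole and with the first naming rule.

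For the antibody gates, the same-sign share (99.1%) was 97.8% with gates at 0.1 and 98.2 to 99.0% with 1 capture left out. Pearson r (0.921) was 0.909 with gates at 0.5, 0.881 with gates at 0.1, 0.946 for genes of at least 50 CPM and 0.898 to 0.907 with 1 capture left out. Spearman rho (0.878) was 0.864, 0.827, 0.918 and 0.844 to 0.854 under those settings and 0.886 with antibody shares. With antibody shares in place of counts, the level relative to the library median was 1.70 in place of 1.76 for CXCR4 in DZ-like cells, 4.32 in place of 16.3 for CD9 and 1.59 in place of 6.82 for CD44 in plasmablast-like cells. In pre-memory-like cells it was 0.58 in place of 4.45 for CCR6, 0.762 in place of 4.84 for CD69 and 2.80 in place of 19.4 for CD44. Thus CCR6 and CD69 turned from above the median to below it there, as did CD9 (0.204 in place of 1.92), and in plasmablast-like cells CCR6 (0.23 in place of 1.55) and CD69 (0.284 in place of 1.40). The rho of antibody and own transcript, as a mean of both captures, was 0.416 with shares and 0.333 with thinned cells for CXCR4 (0.50 as reported), 0.316 and 0.255 for CD83 (0.33), 0.422 and 0.238 for CD9 (0.438), 0.0385 and 0.083 for CCR6 (0.111), -0.0105 (reversed) and 0.051 for CD69 (0.095), and 0.192 and 0.119 for CD44 (0.240). In capture a the transcripts of CCR6, CD69, CD44 and CD9 stood at 6.12, 4.55, 12.3 and 19.1 CPM; whether depth limits them was not tested.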

Other observations

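The tests on total GC were written before their results were seen, except the fold test without plasmablast-like cells and other types; that test and the test of the antibody-gate slope were chosen only after the results had been seen.

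Apart from TRAC and TRBC2, the transcripts of other cell types given here were scarce in these libraries but uneven. The T cell receptor transcript TRAC stood at 144 to 172 CPM in the 6 sorted libraries and 118 and 117 CPM in captures a and b, while the T cell genes CD3D and CD3E reached at most 1.04 and 0.894 CPM. GNLY, a granule gene of NK cells, stood at 5.29 CPM in LZ 1 and 5.83 CPM in total GC 1 and at most 0.383 CPM elsewhere. LYZ, a myeloid gene, reached 22.8 CPM in total GC 1 and at most 3.54 CPM elsewhere, and GZMB 18.4 CPM in DZ 1 and 15.1 CPM in total GC 1. JCHAIN, which joins secreted antibodies, ran from 176 CPM in LZ 1 to 663 CPM in total GC 2. TRBC2 ran from 17.4 to 18.5 CPM in the sorted libraries of donor 1 and from 41.1 to 52.3 CPM in those of donor 2.

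Among cells called S or G2/M, 61.9% and 62.8% were called G2/M in the DZ libraries of donors 1 and 2 and 41.1% and 37.1% in the LZ libraries. In DZ 1 the median was 5516 UMIs in these cells and 3364 in G1-called cells, and in LZ 1 it was 7387 and 4188.5.

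With the donor as a block, 337 genes were higher in total GC than in the mean of the gates. A difference in depth is argued against: with totals thinned to the smallest library, 93.77% of them (316) were still called. Because the mean was taken on the log scale, genes that differ between the gates could stand above it without any other source. Against the arithmetic mean of the gates the median log2 was 0.2827 (0.240 and 0.326 in donors 1 and 2), which falls between the bounds of 0.1 and 0.3 set for both donors. Of the 337 genes 304 (90.2%) lay above that mean in both donors, which goes against the log scale as the whole source, but they had been picked for high levels in the same total GC libraries, so this stays open. Without plasmablast-like cells and other cell types 79.53% of the genes (268) were still called, which falls between the planned bounds of 50% and 80%, so the folds were compared. For 289 genes outside the plasmablast, immunoglobulin and other-cell-type lists the median ratio of the log2 change without those cells to the one with them was 1.038 (1.033 to 1.042 on resampled genes, 283 genes tested; 258 still called). That argues against those cells for these genes as a set, but not for 12 of them whose change fell under 0.5 of its size, such as CKAP4 (0.93 to -0.02), FAM46C (1.51 to -0.29) and CCL4 (2.51 to 0.28), or for 6 that could no longer be tested. For the other 48 genes the ratio was 0.512 (0.451 to 0.643, 46 tested), the median log2 went from 0.982 to 0.535 and 10 were still called, which leaves those cells open as a source for this part. Of the 337 genes, 67 stood above both gates in both donors. GC cells outside both gates were not tested as a source.

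The antibody gates gave smaller RNA differences than the sort, with a slope of 0.645, and a hypothesis is that wide gates mix cells of both states. The slope over called genes was 0.478 with gates at 0.5 of the cells, 0.645 at 0.333 and 0.915 at 0.1. It rose in both captures (0.467, 0.671 and 0.874 in a, and 0.489, 0.619 and 0.957 in b), as that hypothesis predicts. Narrower gates could widen the RNA difference under other explanations too, so the rise does not decide between them. The narrowest gates held 101 and 58 cells in the CXCR4-high gate and 142 and 90 in the CD83-high gate of a and b. A difference between donors or kits stays open, since donor 3 was not sorted by zone.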
